A study of Homo sapiens with 6 samples.

How the data were processed

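The data were RNA sequencing read counts from DBTRG, a human glioblastoma cell line, grown for 5 days either on a rigid dish in 2D or in a soft gel in 3D. Each group had 3 libraries, numbered 1 to 3 in the labels. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with an Illumina TruSeq RNA kit. The labels do not say whether replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The labels name no batch, strand setting or sequencing run.

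The submitters' processing notes name HISAT2, HTSeq and the human genome build hg38, without versions or roles. A single table covered 58884 genes. The authors deposited estimated counts per gene, of which 11.3% to 13.0% of genes per library held decimals. Plain HTSeq output holds whole numbers, and the quantifier is not given in the sources used here. The authors also deposited TPM values, which summed to 985477 to 991371 per library. The authors' deposited comparison of the groups gave a fold (a linear ratio), a log2 fold change, a p-value and an adjusted p-value per gene, and its name refers to DESeq2. The authors' log2 fold changes were smaller than ratios of mean counts for low-count genes. Gene length per the file headers was used only in an added correction and in the gain per kb of histone and olfactory receptor genes.

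Counts were rounded to whole numbers. Library totals ran from 20911363 to 25901499 counts, so that 3 counts, the limit a count of 0 allows, corresponded to 0.116 to 0.143 CPM (counts scaled to library size). Such limits and the counting interval of MGMT cover counting error only, since PCR duplicates are not independent molecules. Genes were filtered with filterByExpr (minimum count 10) and scaled by TMM. The groups were compared with edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3). A gene was called changed at a Benjamini-Hochberg adjusted p below 0.05, and changed at least 2-fold where the absolute log2 fold change was also 1 or more. Fold changes are soft gel over rigid dish, on the log2 scale, and each standard error (SE) was taken from the test statistic. CPM values are means ± SD over 3 libraries after TMM scaling. Gene positions and biotypes came from GENCODE release 29 on hg38, which held 99.5% of the gene identifiers (58611 genes).

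The 37 gene lists, the comparison and the naming rule were fixed in advance. The 37 lists comprised the study's title genes, the signalling, matrix, cell cycle, metabolism, repair, cell state and stress lists named in the results, and markers of 6 other cell types. The named genes were STC1, STAT3 and MGMT, and the 10 protein-coding genes with the largest change in each direction. These had to pass the threshold, average 10 CPM or more and show no overlap between the groups. Up to 2 risen and 2 fallen members per list, with 5 CPM or more, were added. Genes named outside this rule are said to be so. Lists with 5 or more tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 33 lists, with an estimated correlation and fry as alternatives. Current histone symbols are used, where the deposited table has older ones.

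The pipeline was tested on simulated data with 200 changed genes, and 25 more raised 1.5-fold as a list. The shares recovered below cover the 200 genes only. In the simulated comparison of 3 libraries with 3, run on 15803 genes, edgeR recovered 13.4% of genes changed 1.5-fold and 64.3% of those changed 2-fold, and 4.82% of called genes were false. Changes of 1.5-fold were therefore often missed in this simulation. DESeq2 called 18.9% falsely in the same simulation. The real comparison called far more genes (4603) than were changed in the simulation, so these shares may not carry over to it.

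The alternatives chosen before the data were examined were DESeq2 size factors, upper quartile factors, no low-count filter, a filter of 1 CPM in 3 libraries, a replicate block, leaving out each library, DESeq2 (1.42.0), limma-voom, limma on log2(TPM + 1) and log2(TPM + 0.1), protein-coding genes only, and glmTreat against a fold of 1.5. A length correction, a GC correction and a fit without mitochondrial genes were chosen after seeing the data. Pathway enrichment used Fisher's exact test (one-sided, scipy) on KEGG terms of the deposited annotation. The background was the 5720 tested genes with a term, and terms had 10 to 500 tested members. Figures were drawn with matplotlib. Results for some single genes are not reported here.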

Results

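RNA of DBTRG cells, an established human glioblastoma line, was sequenced after 5 days on a rigid dish (2D) or in a soft gel (3D), with 3 libraries per group. The rigid dish libraries held 25901499, 24170047 and 23944278 counts and the soft gel libraries 23483446, 24135884 and 20911363. Libraries of 1 group correlated at 0.972 to 0.985 (Pearson, log2 CPM across genes, which are not independent replicates) and libraries of different groups at 0.945 to 0.966. The first principal component held 57.6% of the variance and separated the groups. The second held 17.4% and set rigid dish 1 (49.05) apart from rigid dish 2 (-4.56) and rigid dish 3 (-26.83). Soft gel 1 (6.82), soft gel 2 (-0.41) and soft gel 3 (-24.06) lay in the same order by number.

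The series title concerns STC1, temozolomide resistance, STAT3 and MGMT, so these genes were examined first. STC1, which encodes the secreted glycoprotein stanniocalcin-1, was higher in soft gel, at 308 ± 14.2 CPM against 126 ± 17.2 CPM on the rigid dish (SD, n = 3 each). STAT3, a transcription factor activated by cytokines, was slightly lower, at 178 ± 17.1 against 224 ± 4.56 CPM. MGMT, which encodes the DNA repair enzyme that removes alkyl groups from guanine, was close to the detection limit in both groups. Its counts were 1, 1 and 2 on the rigid dish and 0, 1 and 0 in soft gel. STC1 (ENSG00000159167, hg38 chromosome 8, 23841915 to 23854807, minus strand) had a log2 fold change of 1.29 (SE 0.124, edgeR quasi-likelihood adjusted p = 0.000419, Benjamini-Hochberg), with every soft gel library above every rigid dish library. STAT3 (ENSG00000168610, chromosome 17, 42313324 to 42388568, minus strand) had a log2 fold change of -0.33 (SE 0.108, edgeR adjusted p = 0.0484). That call was lost on leaving out rigid dish 2 (adjusted p = 0.159), rigid dish 3 (0.0606), soft gel 1 (0.177) or soft gel 2 (0.17), and with upper quartile factors (0.0735), the CPM filter (0.0505), protein-coding genes only (0.0582) or TPM values (0.227 and 0.233), always with the same direction. MGMT (ENSG00000170430, chromosome 10, 129467184 to 129768007, plus strand) fell below the low-count filter. Its ratio of soft gel to rigid dish was 0.27, with a 95% counting interval of 0.0055 to 2.73, so no difference was detectable at this depth.

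**Figure D1:**
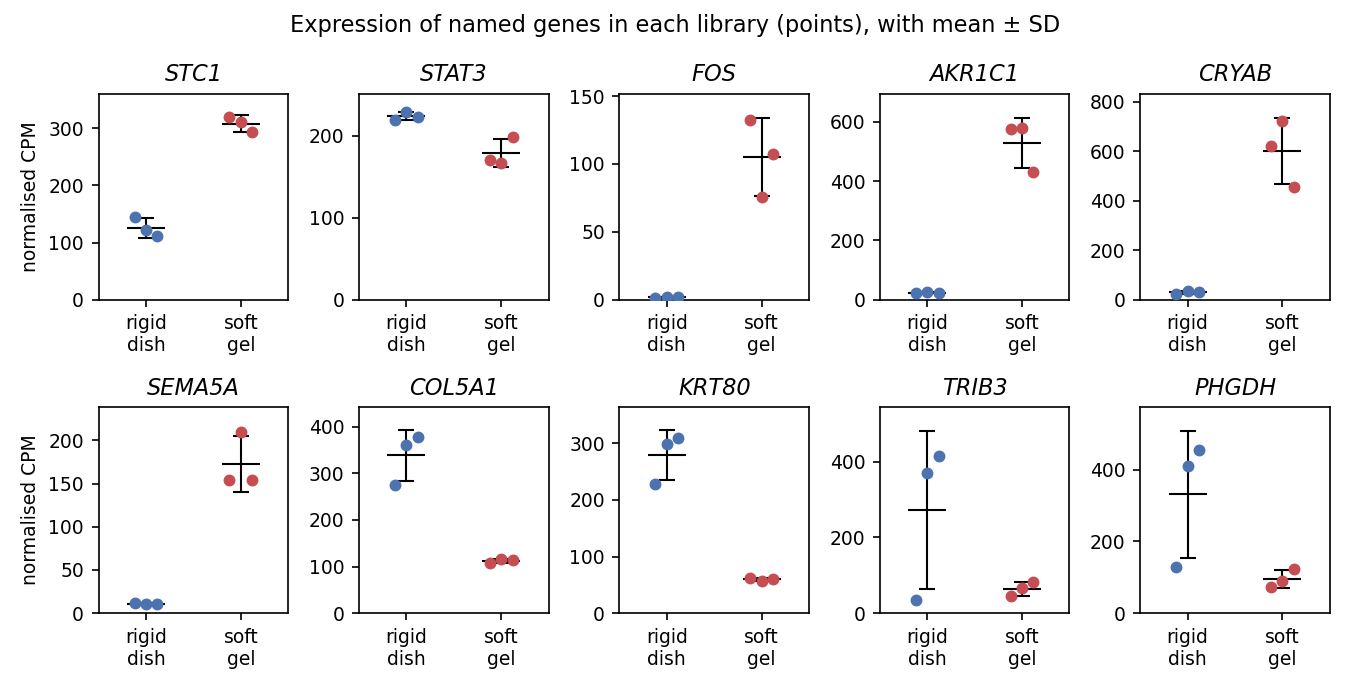
Normalised CPM (y axis, from 0) of 10 genes in each library on the rigid dish (blue) and in soft gel (red), with mean ± SD (n = 3). STC1 lay at 111 to 145 CPM on the rigid dish and 292 to 320 CPM in soft gel, while TRIB3 in rigid dish 1 (33.5 CPM) lay far from rigid dish 2 (369 CPM) and rigid dish 3 (414 CPM).

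By gene lists at a preset inter-gene correlation, histone (8 of 11 risen) and mitochondrially encoded genes (12 of 13) were mostly higher in soft gel, and ribosomal protein (27 of 28 fallen), S phase (21 of 26) and contractile cytoskeleton genes (15 of 22) mostly lower. None of these list calls was kept with an estimated correlation. Of 16098 genes tested, 4603 (28.6%) differed by edgeR's quasi-likelihood test, 2480 higher and 2123 lower in soft gel. Which direction held more genes depended on the scaling, with 2268 higher and 2447 lower with DESeq2 size factors and 2716 higher and 1885 lower with upper quartile factors. At least 2-fold changes were mostly rises, with 1080 genes higher and 314 lower. Among 13498 protein-coding genes, 2040 were higher and 2047 lower, whereas among 2600 genes of other biotypes 440 were higher and 76 lower. The median log2 fold change was 0.38 for 625 lincRNA genes and 0.32 for 770 antisense genes, against 0.01 for protein-coding genes. Reads of the 380 olfactory receptor genes, taken as background, were also higher, at 16.2 to 22.4 CPM in soft gel against 7.81 to 12.05 CPM on the rigid dish, and their part in the rise of other biotypes was not tested. Antisense genes are uncertain, because no strand setting is stated. The groups did not overlap for 7182 genes (44.6%, against 10% by chance for each gene). Genes of the same libraries vary together, so this share does not count as separate tests. Leaving out rigid dish 2, soft gel 1 or soft gel 2 reduced the count to 2026, 1963 or 1803 genes, and without rigid dish 3, 43.1% of 3180 calls were higher.

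**Figure D2:**
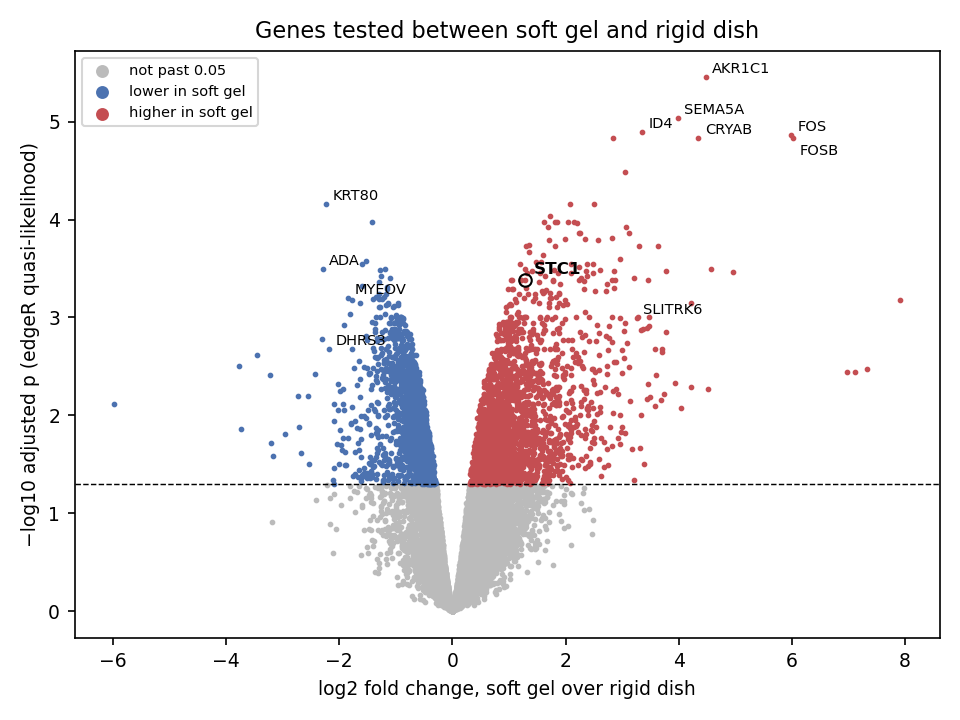
Log2 fold change (x axis, soft gel over rigid dish) and -log10 of the edgeR adjusted p (y axis) for each of 16098 genes tested, with the dashed line at 0.05. Red points (2480 genes) were higher and blue points (2123 genes) lower in soft gel, and STC1 is circled.

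The 10 largest rises among well-expressed protein-coding genes began with FOSB and FOS, immediate early transcription factors of the AP-1 family. FOSB went from 0.817 ± 0.213 to 54.1 ± 15.8 CPM and FOS from 1.66 ± 0.459 to 105 ± 28.7 CPM (SD, n = 3). AKR1C1, an aldo-keto reductase of steroid metabolism, rose from 23.7 ± 1.59 to 529 ± 83.9 CPM, and CRYAB, a small heat shock protein, from 29.5 ± 5.65 to 600.5 ± 133.6 CPM. SEMA5A, an axon guidance semaphorin, rose from 10.9 ± 0.963 to 173 ± 32.2 CPM. The log2 fold changes were 6.02 for FOSB, 5.99 for FOS, 4.48 for AKR1C1, 4.35 for CRYAB and 3.98 for SEMA5A. The edgeR adjusted p was 3.54e-06 for AKR1C1, 9.12e-06 for SEMA5A, 1.38e-05 for FOS, and 1.48e-05 for FOSB and CRYAB. ID4, an inhibitor of basic helix-loop-helix factors (3.36), SLITRK6 (3.26), the axon guidance gene DRAXIN (3.13), the phospholipase receptor PLA2R1 (3.05) and HHIPL2 (2.96) completed the set. AKR1C1 and AKR1C2 are near-identical copies whose reads the counting could split, so their separate levels are uncertain. These 10 genes kept their calls under all alternatives run.

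The 10 largest falls were led by ADA, the adenosine deaminase gene, from 56.0 ± 14.5 to 11.5 ± 1.01 CPM (log2 fold change -2.28). KRT80, an epithelial-type keratin, fell from 279 ± 44.2 to 59.5 ± 2.98 CPM (-2.23). DHRS3, a retinal reductase, fell from 81.7 ± 29.6 to 18.1 ± 6.75 CPM (-2.17). The edgeR adjusted p was 0.000322 for ADA, 6.92e-05 for KRT80 and 0.00211 for DHRS3. MYEOV (-1.83), the metallothionein MT1E (-1.80), the cell cycle transcription factor MYBL2 (-1.64), the fibrillar collagen COL5A1 (-1.60), SPANXA2 (-1.59) and the actin regulator MICAL2 (-1.52) followed. SPANXA2 and MT1E belong to families of near-identical genes, so their levels are uncertain. PHGDH, the first enzyme of serine synthesis, was lower (-1.79, edgeR adjusted p = 0.0123), but rigid dish 1 held 129 CPM against 410 CPM in rigid dish 2 and 455 CPM in rigid dish 3. Its call was lost without soft gel 1 (adjusted p = 0.0556) or soft gel 2 (0.0615).

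Of 33 gene lists with enough tested members, 16 passed camera at an adjusted p below 0.05, while 0 passed camera with an estimated correlation (5 at an unadjusted p below 0.05) and 16 passed fry, which tests a list without reference to other genes. The lists that passed fry were not the same, since 5 camera calls were lost and 5 gained. Those gained by fry were structural matrix (adjusted p = 0.0402), NF-kB (0.0411), stem and progenitor (0.0225), TGF-beta (0.0411) and oxidative stress genes (0.0411). Tested cell cycle genes that passed were lower in soft gel. In the S phase list, 21 of 26 tested members fell and 0 rose (23 fell adjusted over the list alone), with camera adjusted p = 4.81e-11, and adjusted p = 0.528 with an estimated correlation. MCM5, a subunit of the replicative helicase, went from 162 ± 8.11 to 73.3 ± 9.63 CPM, and GINS2 from 22.7 ± 2.30 to 10.6 ± 2.19 CPM. In the G2 and mitosis list, 15 of 26 fell and 0 rose (18 fell adjusted over the list alone), with camera adjusted p = 3.13e-07, and adjusted p = 0.575 with an estimated correlation. That list did not pass fry (adjusted p = 0.0644). CDC20, an activator of the anaphase-promoting complex (log2 fold change -1.26), and BIRC5, survivin (-1.004), fell most among members with enough counts. The S phase count fell to 13 without soft gel 1 and 10 without soft gel 2, and ran from 7 to 24 under the alternatives that kept all libraries. In the G2 and mitosis list, 12 to 20 fell and 0 to 2 rose on leaving out 1 library. With all libraries kept, the alternatives gave 9 to 21 fallen and 0 to 2 risen in that list.

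Replication-dependent histone genes moved the other way, with 8 of 11 tested members higher and 0 lower (9 higher adjusted over the list alone). Their median log2 fold change was 1.59 (camera adjusted p = 0.000113, and adjusted p = 0.27 with an estimated correlation). H2AC6 rose from 3.61 ± 0.795 to 13.3 ± 1.59 CPM and H2BC21 from 3.53 ± 1.31 to 10.6 ± 0.792 CPM. These genes are members of a multi-copy family with similar sequences, so single genes are uncertain. The count was 5 without rigid dish 2, soft gel 1 or soft gel 2.

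Cytosolic ribosomal protein genes fell almost as a block, 27 of 28 (28 adjusted over the list alone), with a median log2 fold change of -0.71 (camera adjusted p = 8.89e-14, and adjusted p = 0.528 with an estimated correlation). RPLP0 went from 2403 ± 571 to 1255 ± 96.3 CPM. Fallen ribosomal protein genes ran from 18 to 28 on leaving out 1 library. Ribosomal protein genes took 4.04% ± 0.354 of counts on the rigid dish and 2.69% ± 0.223 in soft gel. Mitochondrially encoded genes rose, 12 of 13 (12 adjusted over the list alone), with a median of 0.91 (camera adjusted p = 3.52e-07, and adjusted p = 0.519 with an estimated correlation). MT-ND2 went from 2815 ± 509.5 to 6108 ± 752 CPM and MT-CYB from 1670 ± 210.3 to 3370 ± 238 CPM. Risen mitochondrially encoded genes ran from 9 to 12 on leaving out 1 library. Mitochondrial mRNA took 4.15% ± 0.340 of counts on the rigid dish and 7.58% ± 0.551 in soft gel (exact permutation p = 0.1, the smallest that 3 against 3 allows, two-sided). Of 25 nuclear genes of oxidative phosphorylation, 3 rose and 0 fell (camera adjusted p = 0.297). On leaving out 1 library, 0 to 2 of these nuclear genes rose and 0 to 2 fell.

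Contractile cytoskeleton genes were mostly lower. In the SRF and MRTF list of actin cytoskeleton genes, 15 of 22 fell and 0 rose (16 fell adjusted over the list alone), with camera adjusted p = 1.46e-07, and adjusted p = 0.328 with an estimated correlation. FLNA, filamin A, went from 5098 ± 868 to 2864 ± 275 CPM and CNN2, calponin 2, from 471 ± 63.7 to 233 ± 33.1 CPM. ACTA2, TAGLN and CNN1, named outside the rule, did not pass (edgeR adjusted p = 0.44, 0.148 and 0.0701). Fallen members of this list ran from 10 to 16 on leaving out 1 library. Of 22 YAP and TEAD targets, 10 fell and 2 rose (13 and 2 adjusted over the list alone), with camera adjusted p = 0.000528, and adjusted p = 0.314 with an estimated correlation. F3, tissue factor (-1.20), and AXL, a receptor tyrosine kinase (-0.97), fell, while DOCK5 (0.67) and CRIM1 (0.61) rose. The targets CCN1 (-0.41), CCN2 (-0.27) and ANKRD1 (0.02), named outside the rule, did not pass (edgeR adjusted p = 0.0532, 0.132 and 0.9). The number of fallen YAP and TEAD targets was 5 without rigid dish 2, and 6 without soft gel 1 or soft gel 2.

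Matrix genes moved in both directions. Of 25 structural matrix genes, 10 fell and 5 rose (12 and 6 adjusted over the list alone), with camera adjusted p = 0.058. COL5A1 and COL12A1 (-1.17) fell, and SPARC, a collagen-binding matrix protein, rose from 848 ± 107 to 1296 ± 33.5 CPM. The camera call was gained without rigid dish 1 (adjusted p = 0.0427), soft gel 1 (0.0186) or soft gel 2 (0.0286). Of 19 matrix proteases, crosslinkers and inhibitors, 6 fell and 4 rose (camera adjusted p = 0.297, and 0.028 without rigid dish 1). PLAT, tissue plasminogen activator (-1.24), and LOXL2, a collagen crosslinking enzyme (-1.19), fell. Of 19 integrin and focal adhesion genes, 5 rose and 2 fell (camera adjusted p = 0.669), including ITGA1 (1.61), and the list's median (-0.0048) and mean (0.20) differed in sign.

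Among glioma cell states, mesenchymal genes that passed were mostly lower and astrocyte genes that passed mostly higher. Of 24 mesenchymal genes, 11 fell and 1 rose (11 and 1 adjusted over the list alone), with camera adjusted p = 0.000416, and adjusted p = 0.575 with an estimated correlation. That list did not pass fry (adjusted p = 0.0556). LGALS1, galectin-1, went from 915 ± 152 to 358 ± 32.6 CPM and S100A10 from 246 ± 47.3 to 115 ± 20.5 CPM. The number fallen was 7 without rigid dish 2, and 6 without soft gel 1 or soft gel 2. Of 17 astrocyte genes, 7 rose and 1 fell (7 and 1 adjusted over the list alone), with camera adjusted p = 0.0116, and adjusted p = 0.314 with an estimated correlation. The largest rises were CRYAB and APOE, a lipid carrier, which went from 6.73 ± 2.74 to 44.2 ± 8.34 CPM. The number risen was 3 without soft gel 1 or soft gel 2. Of 22 stem and progenitor genes, 7 rose and 2 fell (camera adjusted p = 0.297), with ID1 higher (1.07) and HES1 lower (-1.24). Of 16 epithelial-mesenchymal regulators, 3 rose and 3 fell (camera adjusted p = 0.421), and CLDN1, a tight junction protein, fell (-1.17). On leaving out 1 library, 0 to 4 of these regulators rose and 1 to 6 fell.

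Of 20 STAT3 targets, 8 fell and 2 rose (11 and 3 adjusted over the list alone), with camera adjusted p = 0.013, and adjusted p = 0.575 with an estimated correlation. The list did not pass fry (adjusted p = 0.124). BCL3 (-1.22) and MYC (-1.08) fell, whereas FOS, which is also an immediate early gene, rose. The number fallen was 4 without rigid dish 2, soft gel 1 or soft gel 2. The list holds STAT3 itself. Of 21 immediate early and dissociation stress genes, 8 rose and 3 fell (10 and 3 adjusted over the list alone), with camera adjusted p = 0.013, and adjusted p = 0.575 with an estimated correlation. FOSL1 (-0.87) and the heat shock gene HSPB1 (-0.96) fell, against the direction of FOS and FOSB. The number risen was 5 without rigid dish 2 or soft gel 1. Of 21 NF-kB and cytokine genes, 3 rose and 0 fell (camera adjusted p = 0.0743, and 0.014 without soft gel 2), among them CXCL8, interleukin-8 (1.53), and TNFAIP3 (1.15). Of 22 interferon response genes, 6 rose and 2 fell (camera adjusted p = 0.17). Of 25 TGF-beta and SMAD targets, 8 rose and 4 fell (camera adjusted p = 0.677), with ID2 from 37.6 ± 8.0 to 213 ± 9.25 CPM.

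Some DNA repair genes, which bear on alkylating drugs such as temozolomide, were lower, while most tested members of both repair lists did not pass. Whether their fall was separate from that of the S phase genes (21 of 26) was not tested. In the list of alkylation, mismatch and base excision repair, 9 of 26 fell and 1 rose (12 and 1 adjusted over the list alone), with camera adjusted p = 0.00135, and adjusted p = 0.27 with an estimated correlation. LIG1, the replicative DNA ligase, went from 68.9 ± 8.96 to 38.6 ± 1.075 CPM. The number fallen was 5 without rigid dish 2, 4 without soft gel 1 and 3 without soft gel 2. In the homologous recombination and Fanconi list, 7 of 25 fell and 0 rose (7 adjusted over the list alone), with camera adjusted p = 0.0153, adjusted p = 0.575 with an estimated correlation and fry adjusted p = 0.147. The camera call was lost without rigid dish 1 (camera adjusted p = 0.179) or soft gel 3 (0.0924), and the number fallen was 4 without rigid dish 2, 1 without soft gel 1 and 2 without soft gel 2. Under the alternatives that kept all libraries, the number fallen ran from 0 to 14 in this list and from 2 to 14 in the list of alkylation, mismatch and base excision repair. Of 15 drug efflux transporters, 2 rose and 1 fell (camera adjusted p = 0.75), and ABCC2, a multidrug resistance transporter, rose from 8.46 ± 0.462 to 24.4 ± 4.39 CPM. Of 24 p53 targets, 3 rose and 1 fell (camera adjusted p = 0.989), with ZMAT3 (0.95) and RRM2B (0.90) higher, and the median (-0.03) and mean (0.05) differed in sign.

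Of the lists of sterol, lysosome, oxidative stress, hypoxia and lipid genes, those of cholesterol synthesis and of autophagy and lysosome passed camera. Of 24 cholesterol synthesis genes, 10 rose and 0 fell (11 and 1 adjusted over the list alone), with camera adjusted p = 0.00217, and adjusted p = 0.575 with an estimated correlation. The sterol enzymes SC5D (1.17) and MSMO1 (1.16) rose most. The number risen was 5 without rigid dish 2 or soft gel 2, and the camera call was lost without soft gel 3 (adjusted p = 0.0834). Of 26 autophagy and lysosome genes, 12 rose and 1 fell (12 and 2 adjusted over the list alone), with camera adjusted p = 0.00285, adjusted p = 0.634 with an estimated correlation and fry adjusted p = 0.0686. NPC2, a lysosomal cholesterol carrier (1.36), and NEU1, a lysosomal sialidase (1.10), rose. Of 24 oxidative stress and NRF2 genes, 7 rose and 0 fell (camera adjusted p = 0.175), led by AKR1C1 and AKR1C2. Of 29 hypoxia and glycolysis genes, 7 fell and 4 rose (camera adjusted p = 0.297), with LDHA, lactate dehydrogenase A, lower (-1.02) and CA12, a carbonic anhydrase, higher (2.10). Of 22 fatty acid genes, 6 rose and 5 fell (camera adjusted p = 0.909), with PPARGC1A higher (1.04) and SREBF1 lower (-1.33), and the median (-0.04) and mean (0.08) differed in sign.

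In the amino acid and ER stress list, 9 of 24 fell and 2 rose (15 and 3 adjusted over the list alone), with camera adjusted p = 0.0743. TRIB3, an inhibitor induced by ATF4, was at 33.5, 369 and 414 CPM in rigid dish 1, 2 and 3, and at 45.2, 65.3 and 82.0 CPM in soft gel (edgeR adjusted p = 0.0498). DDIT4 was at 9.21, 68.3 and 68.4 CPM on the rigid dish and at 10.2, 14.2 and 11.8 CPM in soft gel (edgeR adjusted p = 0.0317). Rigid dish 1 thus lay at the level of the soft gel libraries for both genes. The number fallen was 14 without rigid dish 1 (camera adjusted p = 1.84e-05), 2 without rigid dish 2, 5 without rigid dish 3, 1 without soft gel 1 and 0 without soft gel 2. The TRIB3 call was lost on leaving out rigid dish 2 (adjusted p = 0.135), rigid dish 3 (0.111), soft gel 1 (0.152), soft gel 2 (0.149) or soft gel 3 (0.0648). The same libraries ended the DDIT4 call (0.102, 0.0686, 0.107, 0.0953 and 0.0595). DNAJB9, an ER chaperone partner, rose from 13.4 ± 1.80 to 36.8 ± 4.21 CPM.

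For lists that did not pass camera, risen and fallen members adjusted over the list alone were as follows. There were 5 and 3 integrin genes, 5 and 7 proteases and crosslinkers, 7 and 5 stem and progenitor genes, and 4 and 4 epithelial-mesenchymal regulators. There were 3 and 0 NF-kB genes, 8 and 2 interferon response genes, 9 and 5 TGF-beta targets, 2 and 1 efflux transporters, and 3 and 1 p53 targets. There were 7 and 0 oxidative stress genes, 4 and 7 hypoxia genes, 7 and 6 fatty acid genes, 1 and 0 oxidative phosphorylation genes, 1 and 1 neuronal markers, and 1 and 1 endothelial markers. Leaving out single libraries changed several of the counts over all genes, such as 2 to 8 risen interferon genes, 3 to 7 risen oxidative stress genes and 2 to 7 fallen fatty acid genes.

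**Figure D3:**
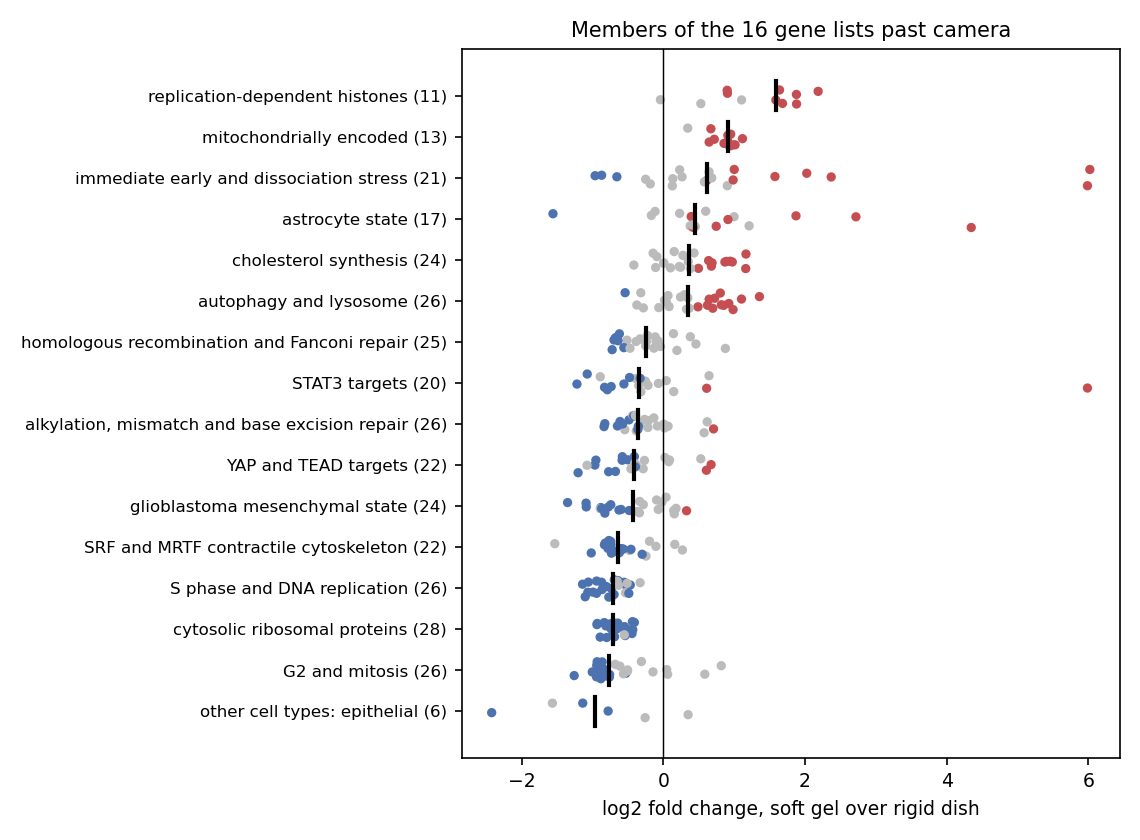
Log2 fold change (x axis, soft gel over rigid dish) of each tested member (points) of the 16 gene lists that passed camera, with the number tested in parentheses and the list's median as a black bar. Red points rose, blue points fell and grey points did not pass edgeR at 0.05, and medians ran from -0.96 for epithelial markers to 1.59 for histones.

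Markers of other cell types were examined in the same fit. Of 6 tested epithelial markers, 3 fell and 0 rose (3 adjusted over the list alone), with camera adjusted p = 0.0199, and adjusted p = 0.528 with an estimated correlation. KRT18, a keratin many tumour lines express, went from 275 ± 53.2 to 125 ± 9.61 CPM. The call was lost without rigid dish 3 (camera adjusted p = 0.0516), and 5 markers fell without rigid dish 1. Of 8 neuronal markers, 1 rose and 1 fell (camera adjusted p = 0.502), and of 5 endothelial markers, 1 fell and 0 rose (camera adjusted p = 0.599). Too few members were tested of the immune (4 of 16), oligodendrocyte (4 of 10) and erythroid (3 of 10) lists. Without a low-count filter, which admitted genes with few reads, 4 immune and 3 erythroid markers rose and 0 fell with all libraries kept. With the filter, 2 of 5 immune markers rose on leaving out any library but rigid dish 1. CD68, a lysosomal protein listed as an immune marker, rose from 12.01 ± 2.54 to 41.1 ± 3.82 CPM. The hemoglobin genes HBA1, HBA2 and HBB, named after their values were seen, together had 2345, 0 and 856 reads on the rigid dish and 6306, 3439 and 5312 reads in soft gel, and did not pass the test (edgeR adjusted p = 0.0777, 0.0901 and 0.0926).

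The authors' deposited table tested 29386 genes and held 5036 with an adjusted p below 0.05, of which 2314 were higher and 2722 lower in soft gel. It marked 950 genes as significant, 693 higher and 257 lower, all with an absolute log2 fold change of 1 or more. Of the 4603 genes called here, 4234 were also past 0.05 in the authors' deposited table, all in the same direction. Both lists rest on the same libraries, so their overlap is not independent support. In the authors' deposited table the log2 fold change was 1.19 for STC1 (adjusted p = 3.251e-16), -0.37 for STAT3 (0.0221) and -0.15 for MGMT (adjusted p = 1).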

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

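The length correction (5001 genes, 2271 higher and 2730 lower), GC correction (5504, 2548 higher and 2956 lower) and fit without mitochondrial genes (4658) were chosen after seeing the data. No gene also called under an alternative gene test turned direction. With TPM values, log2(TPM + 1) called 2313 genes (1345 higher, 968 lower) and log2(TPM + 0.1) 2287 (1327 higher, 960 lower). At least 2-fold, log2(TPM + 1) called 596 (491 higher, 105 lower) and log2(TPM + 0.1) called 157 lower. Without a low-count filter 502 genes were lower at least 2-fold, and glmTreat called 648 genes. The causes were not tested. Leaving out a library gave 1803 to 6164 genes (1006 to 3239 higher, 797 to 2925 lower), and 750 to 1873 at least 2-fold (591 to 1451 higher, 159 to 461 lower). STAT3 was weaker with upper quartile factors (-0.29), the CPM filter (-0.31), log2(TPM + 1) (-0.23), log2(TPM + 0.1) (-0.23) and protein-coding genes only (-0.29), and ran from -0.47 to -0.28 without single libraries. STC1 ran from 1.14 to 1.40. Without single libraries 14 to 18 lists passed camera, and without a low-count filter 19. Of 33 lists, 0 passed camera with an estimated correlation. Whether replicate numbers pair the libraries stays unsettled. Across the groups, deviations of libraries with the same number correlated at 0.209, 0.0084 and 0.283, and those with different numbers at -0.281 to 0.1205. The replicate block called 6442 genes, 4580 of them shared. In simulated data without pairing, the block called fewer genes than the fit without it (72 against 83). Of 108 named gene values, 78 to 103 kept their call without single libraries. MGMT had 4 reads on the rigid dish and 1 in soft gel, at 0.1 TPM or less per library, too few to compare the groups.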

Other observations

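The pathway tests and the tests of explanations below were all chosen after the results were seen. Among genes higher at least 2-fold, 1 of 298 KEGG pathways passed an adjusted p below 0.05 (Fisher's exact test, Benjamini-Hochberg), neuroactive ligand-receptor interaction, with 21 of 100 tested members against 6.49 expected (adjusted p = 0.000337). Background reads over olfactory receptor genes were also higher in soft gel (16.2 to 22.4 CPM against 7.81 to 12.05 CPM), and their part in this pathway was not tested. Pathway members named here were chosen after their values were seen. Its members include the receptor genes C3AR1, CYSLTR1, EDNRB, FPR1, HTR2A, MC1R, MC4R and P2RY1. Hematopoietic cell lineage did not pass (adjusted p = 0.0861), with 9 of 43 higher: CD22, GP1BA, IL3RA, IL6R, IL7R, ITGA1, ITGAM, ITGB3 and KIT. Whether any of these genes share a source with the hemoglobin reads described below was not tested. Among genes lower at least 2-fold, 3 pathways passed. Glycine, serine and threonine metabolism had 6 of 35 (PHGDH, PSAT1, SHMT2, PIPOX, CBS and its near-identical copy CBSL, adjusted p = 0.0249). The copies may share reads, and whether this call holds with them counted as 1 gene was not tested. The adjusted p of the cell cycle and of complement and coagulation depends on this pathway's rank, so their calls are uncertain too. The cell cycle had 11 of 124, among them MCM2, MCM5, MCM6, CDC20 and MYC (adjusted p = 0.0249). Complement and coagulation had 6 of 43, among them PLAT, PLAU and F3 (adjusted p = 0.0494), while 7 others of the 43 were higher at least 2-fold (adjusted p = 0.339). PSAT1 stood at 121 CPM in rigid dish 1 against 526 and 469 CPM in rigid dish 2 and 3, and at 86.6, 139.5 and 168 CPM in soft gel.

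Of the 10 splits of the 6 libraries into 3 and 3, 1 (the real one) gave 4603 genes, and the highest of the others gave 0 by edgeR at an adjusted p below 0.05. The splits are too few for a share under 0.05. Every other split mixes libraries of both groups, so a group difference widens its spread and lowers its calls. The contrast therefore cannot exclude chance. At an unadjusted p below 0.05 the real split had 6919 genes and the highest other 2827, and DESeq2 called 5290 and 429. That other split set rigid dish 1, soft gel 1 and soft gel 2 against the rest.

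Replication-dependent histone genes were higher in soft gel. More cells in S phase would raise S phase genes too, but 21 S phase members fell and 0 rose, and 0 rose under any alternative. More RNA without poly(A) tails would raise other such RNA. The log2 of the summed CPM of 2021 snRNA, scaRNA, rRNA, 7SK, 7SL, RMRP and RPPH1 genes differed by -0.4431 (SE 0.441). That lay below the histones' median of 1.59 by more than 2 standard errors. The sum varied from 26.1 CPM in soft gel 1 to 75.1 CPM in rigid dish 3. Single tested genes went both ways, with a median log2 fold change of -0.32 for 2 snRNA genes and 1.64 for 1 ribozyme gene, none of which passed. The sum may not stand for histone mRNA, so this explanation stays open. More background reads would raise silent genes alike, and the 380 olfactory receptor genes did hold more reads in soft gel (433, 540 and 338, against 312, 228 and 187), but the histones' median gain per kb was 217.15 times theirs. An effect of the culture on histone mRNA stays open as an untested hypothesis, and single histone genes may share reads.

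Of 17 immediate early genes 7 rose, FOS and FOSB among them, with DUSP1 (log2 fold change 2.37), EGR1 (2.03) and KLF6 (1.00), while JUN (0.23) and IER2 (-0.18) did not pass (genes in this paragraph were named after their values were seen). Heat or proteotoxic stress at harvest would raise heat-inducible genes together. Of 11 tested, CRYAB, HSPH1 (0.99) and HSPA6 (2.40, from 0.220 to 1.18 CPM) rose and 2, HSPB1 and DNAJB1 (-0.66), fell, so members that go both ways leave this open. Induction while cells were released from the gel cannot be told apart from an effect of the culture: 7 members rose and 1 fell, but the labels do not describe the release of the cells, and it would follow the group, which keeps both open.

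Hemoglobin RNA was present in 5 of 6 libraries, with 0 reads in rigid dish 2. A switch by soft gel culture alone would leave every rigid dish library near 0, but rigid dish 1 and 3 held 2345 and 856 reads, far beyond counting error, which argues against it as the whole source. An added effect of the culture stays open. Blood RNA carried into the libraries is a candidate source: S100A8, S100A9 and LYZ, abundant in white blood cells and chosen after their values were seen, had 30 reads in rigid dish 1 and 8 in rigid dish 2, 20 in rigid dish 3, and 137, 83 and 93 in soft gel. Only S100A9 (19, 0 and 4 reads on the rigid dish, 80, 25 and 31 in soft gel) ranked with hemoglobin in both groups, while LYZ (6, 5 and 13, then 38, 36 and 41) and S100A8 (5, 3 and 3, then 19, 22 and 21) did not. ALAS2 and AHSP, also chosen after their values were seen, stayed at 7 reads or fewer per library, and the ratio of HBA2 to HBB stayed within 1.07 to 1.38 in the 5 libraries. Too few libraries and reads keep blood RNA open. Carry-over of reads from another library was not tested.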
